A study of Pseudomonas fluorescens with 2 samples.

How the data were processed

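RNA was sequenced from 2 cultures of the soil bacterium Pseudomonas fluorescens Pf0-1, one of the wild type and one of a mutant whose genotype label names a loss of dndB, dndC, dndD and dndE. Per the labels' protocols, both cultures were grown in Luria-Bertani broth to early log phase, RNA was stabilised before the cells were pelleted, DNA was digested, rRNA was removed and the remaining RNA was fragmented, copied to cDNA and amplified by PCR before Illumina sequencing. There was 1 library per genotype, so no difference has a replicate check and no p-value was computed here.

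Reads were aligned with BWA 0.7.10-r789, per the submitters' processing notes. The program that counted reads, the genome build, the gene annotation, the strand setting and any read filter were not given in the sources used here. The authors deposited an estimated count per gene for each library, headed expected count per the file headers and not scaled for depth. All but 25 genes of the wild type and 21 genes of the mutant had whole estimated counts, as deposited to 2 decimals. The authors' deposited FPKM values, per the file headers, scale those counts to length and depth, and dividing the counts by them showed a length term shorter than the listed gene length by 54.0 bases in the wild type and 53.8 bases in the mutant. A further table by the authors joins both libraries over 5692 genes, with the same counts and FPKM, a deposited log2 ratio of the FPKM values, a deposited p-value and a false discovery rate. In that table the authors' FPKM is 0.001 where a gene had no reads, the false discovery rate reaches 1.01, and the test behind the p-value is not given. A shorter table by the authors holds 10 genes, which are those of the joint table with a deposited false discovery rate of at most 0.001 and an absolute log2 ratio of at least 1.

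Estimated counts were rounded to whole reads and scaled to each library's total, which was 2132087 reads in the wild type and 2117442 in the mutant. Ratios are mutant over wild type on the log2 scale with a pseudocount of 0.5 reads, scaled to each library. A gene passed the level floor if it had at least 50 reads in at least 1 library. Genes were counted by size alone, as at least 2-fold higher or lower. Each ratio has an exact conditional 95% interval (Clopper-Pearson), computed from the reads without a pseudocount. Intervals, and the limit of 3 reads that a count of 0 allows, cover counting error only. No marking of PCR copies was given in the sources used here, and no second culture was measured. A gene with no reads in the mutant is given as a lower bound of its fold, computed against 3 reads and rounded down.

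Genes were named by the deposited locus tag. A gene symbol came from the deposited tables for 421 genes and from a RefSeq table of another strain of the species (assembly GCF_900215245.1, matched by identical protein accession) for 2 genes. Product names are those of the best protein match in the deposited annotation, with a KEGG definition where its E-value was at most 1e-30. No genome sequence of Pf0-1 was used here, so no coordinates are given, and the order of locus tag numbers was taken as the order of genes. Reads in genes that overlap or face each other cannot be assigned by strand.

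The groups, the comparisons, the gene lists and the rule for named genes were fixed before the data were examined. So were the alternatives, except those named below as added after the data were seen. The deposited annotation names dndB alone, and the 3 genes after it were taken as the other deleted genes by their place, after their values were seen. The list of genes beside the deletion was defined as 10 on each side, so its members past these 3 genes rest on that later choice. The rule takes the deleted genes, any of their 10 neighbours on each side that differed at least 2-fold, the 12 genes with the highest and the 12 with the lowest ratio past the floor, every gene of the authors' shorter table, up to 4 members of each list with the largest absolute ratio, and the 5 genes with the highest FPKM in each library. Genes outside the rule are named as chosen after their values were seen. Of 30 lists, defined by symbols and product keywords or, for the genes beside the deletion, by position, 27 had at least 5 genes past the floor. For these, the median ratio was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. This percentile describes these 2 libraries and is not a test of the genotypes.

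The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 for the TMM factors of edgeR 4.0.16 and the size factors of DESeq2 1.42.0, both used only as alternative scalings. The procedure was tested on 20 simulated pairs of libraries for the comparison of wild type and mutant over 5692 genes, with the real totals and 200 genes changed in each pair. Of the genes changed by 1.5-fold, 1.4% passed the 2-fold rule, against 48.2% at 2-fold, 99.6% at 3-fold and 100% at 4-fold. Between 0 and 3 unchanged genes per pair passed it, and the intervals held the true ratio for 95.4% of genes. In a part of the pairs, 6.5% of list medians lay outside the central 95% of random lists. Apart from the genes changed, the simulated libraries differed by counting error alone. These rates therefore leave out the wider spread seen between the real libraries. Alternatives changed the scaling, the pseudocount, the level floor, the fold threshold, the unit, list membership and the authors' filter.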

Results

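Gene expression was measured by RNA sequencing in the soil bacterium Pseudomonas fluorescens Pf0-1. The wild type was set against a mutant whose genotype label names a loss of dndB, dndC, dndD and dndE. Products of dnd genes such as dndC, dndD and dndE make DNA phosphorothioation, a modification in which sulfur replaces an oxygen of the DNA backbone. The modification was not measured here, and the comparison asks how the transcriptome differs when the genes named in the label are lost. There was 1 library per genotype, with 2132087 reads assigned to genes in the wild type and 2117442 in the mutant. Of 5692 genes, 3452 (60.6%) had at least 50 reads in at least 1 library. In both libraries the outer membrane lipoprotein gene oprI (Pfl01_4011) had the highest level, at 64577 FPKM in the wild type and 64883 FPKM in the mutant, followed by a cold-shock protein gene (Pfl01_1929), at 17580 and 17047 FPKM, and by the genes of elongation factor P (Pfl01_3999) and ribosomal protein L7/L12 (rplL, Pfl01_5087). The next was rpsO (Pfl01_0782) in the wild type, at 12508 FPKM, and a porin gene (Pfl01_1777) in the mutant, at 13626 FPKM.

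The dnd genes were nearly absent from the mutant library. The gene of DndB (Pfl01_0738) had 454 reads in the wild type and 16 in the mutant, which is 28.2-fold lower (log2 ratio -4.77, 95% interval -5.64 to -4.10), which fits the genotype label. The next 3 genes, unnamed in the deposited annotation, had no reads in the mutant. They were taken as dndC, dndD and dndE by their place after dndB and after their values were seen, so their absence is no separate check of the label. Against the 3 reads that a count of 0 allows, Pfl01_0739, with 530 reads in the wild type, was at least 175-fold lower. On the same bound Pfl01_0740, with 902 reads, was at least 298-fold lower and Pfl01_0741, with 41 reads, at least 13.5-fold lower. The exact intervals, which also take in the counting error of the wild type reads, ended at log2 ratios of -7.15, -7.92 and -3.40. Together these 4 genes had 1927 reads in the wild type and 16 in the mutant. Of the 20 genes beside them, 12 passed the level floor and 0 of those differed 2-fold, but 10 were higher in the mutant. Their median log2 ratio was 0.30, percentile 99.9 among random lists of the same level, with a range of -0.25 to 0.68. The highest were a tellurite resistance gene (Pfl01_0736, 0.68, 0.28 to 1.09), an acetyltransferase gene (Pfl01_0732, 0.52, -0.10 to 1.18) and a hypothetical protein gene (Pfl01_0737, 0.50, 0.10 to 0.91). With a floor of 200 reads the 6 genes left had a median of 0.06, percentile 80.4. The hypothetical protein gene Pfl01_0727, below the floor, had 16 reads in the wild type and 7 in the mutant, with an interval of -2.71 to 0.18 that includes no difference.

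**Figure D1:**
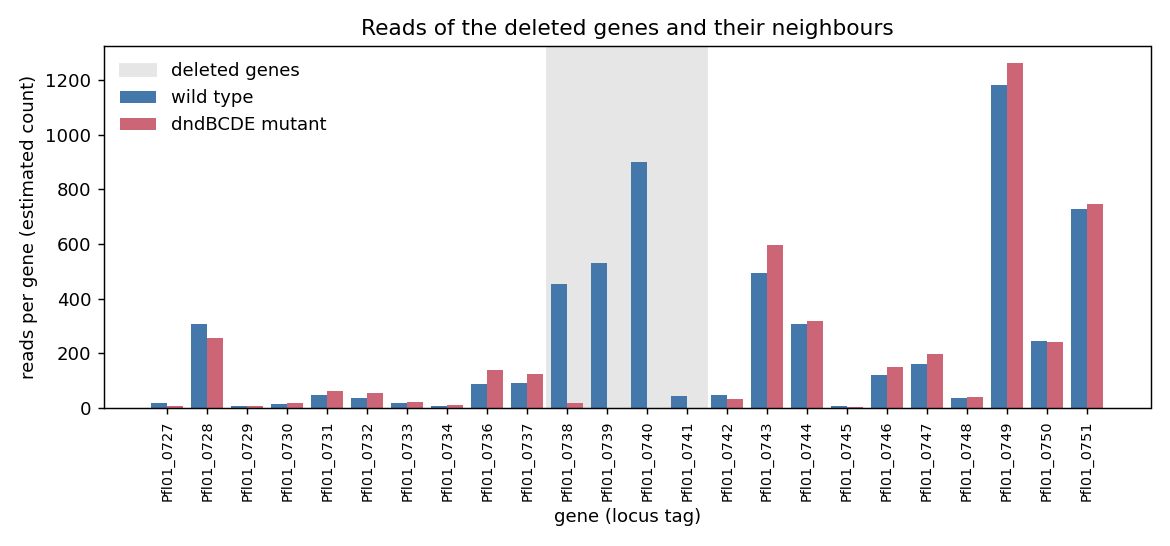
Estimated reads per gene (vertical axis) of the 4 deleted genes and 10 genes on each side, in the order of their locus tags (horizontal axis), in the wild type (blue) and the dndBCDE mutant (red), 1 library each. In the shaded deletion the mutant has 16 reads in Pfl01_0738 and 0 in the next 3 genes, while the genes on both sides have reads in both libraries.

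At least 2-fold higher reads in the mutant were seen for 9 genes past the level floor. The highest ratio was that of Pfl01_1797, the small subunit of xanthine dehydrogenase, an enzyme of purine breakdown, with 141 reads in the wild type and 438 in the mutant (log2 ratio 1.64, 95% interval 1.37 to 1.93). It was the 1 higher gene whose interval lay wholly beyond 2-fold. The large subunit gene beside it (Pfl01_1796, chosen after its value was seen) had a log2 ratio of 0.41 (0.06 to 0.76). The other 8 were the genes of an oxidoreductase (Pfl01_0705, 1.27), a phage tail protein (Pfl01_1150, 1.20), a DNA-binding protein (Pfl01_5492, 1.20), an Ivy-type lysozyme inhibitor (Pfl01_0043, 1.10), a hypothetical protein within a phage tail cluster (Pfl01_1169, 1.06), a phage protein (Pfl01_3496, 1.03), a membrane protein (Pfl01_0900, 1.03) and a hypothetical protein (Pfl01_2488, 1.02). The holin-like gene lrgA (Pfl01_0899), next to Pfl01_0900, had a log2 ratio of 0.98 (0.38 to 1.62).

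At least 2-fold lower reads were seen for 4 genes past the floor, of which 3 were deleted genes. The remaining gene was a nitrate reductase gene (Pfl01_1455), with 56 reads in the wild type and 21 in the mutant (log2 ratio -1.38, 95% interval -2.20 to -0.66). The next lowest ratios were those of the taurine dioxygenase gene tauD (Pfl01_0253, -0.92), whose product releases sulfite from taurine, a cyclic nucleotide-binding protein (Pfl01_1398, -0.91), a ferrioxamine B receptor (Pfl01_0121, -0.83), a gene matched to an arylsulfatase but to an arsenical pump protein in KEGG (Pfl01_2193, -0.81) and a pseudouridine synthase of 16S rRNA (Pfl01_1335, -0.80). The size rule rested on genes of few reads. With no level floor 233 genes were at least 2-fold higher and 134 lower, and with a floor of 200 reads the numbers were 1 and 3.

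**Figure D2:**
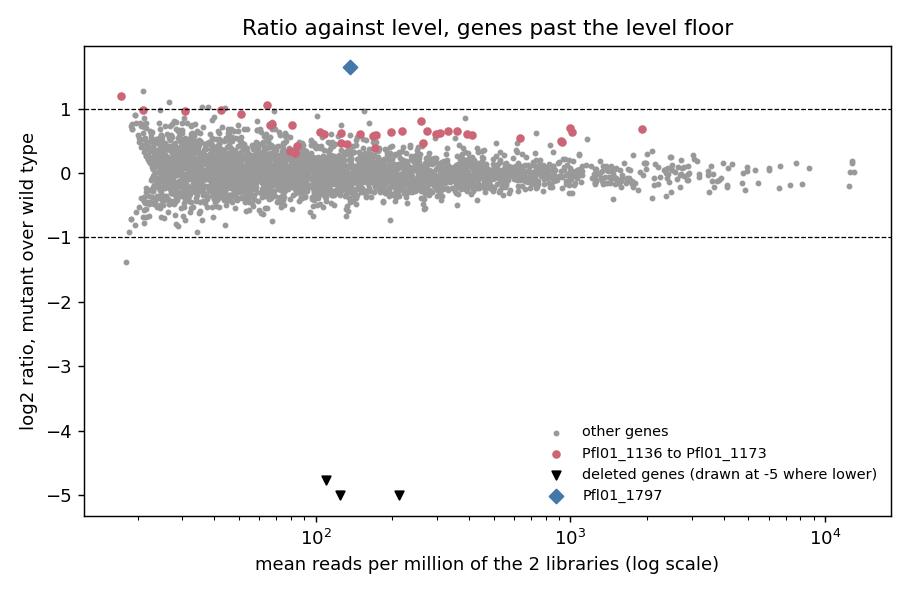
Log2 ratio of mutant over wild type (vertical axis) against the mean CPM of the 2 libraries (horizontal log axis), for the 3452 genes past the level floor, 1 point per gene. Dashed lines mark 2-fold, 3 deleted genes are black triangles (those without mutant reads drawn at -5), Pfl01_1797 is the blue diamond, and the 38 genes of a phage tail cluster (red) all lie above 0, between 0.31 and 1.20.

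The genes of 1 phage tail cluster were higher in the mutant, and with them the list of prophage and bacteriocin genes. Of the 40 members past the floor, 34 had a ratio above 0 and 3 were at least 2-fold higher. The median log2 ratio was 0.59, percentile 100 among random lists of the same level. Without this cluster the percentile was 62.3, but 8 of the 13 genes left were choline genes taken in by a keyword. The cluster is 1 run of adjacent genes, Pfl01_1136 to Pfl01_1173, most of them annotated as phage tail, baseplate or R-type pyocin genes. Genes of this kind encode tailocins, contractile phage tails that kill related bacteria. Others in the run are annotated as hypothetical proteins or otherwise, such as a regulator of the ArsR family (Pfl01_1156). The run, its genes named here and those beside it were chosen after their values were seen, and 27 of its 38 genes were on the list. All 38 genes were higher in the mutant, with log2 ratios from 0.31 to 1.20 and a median of 0.63 (1.55-fold). The interval lay above 0 for 37 of them. Their reads summed to 19688 in the wild type and 29850 in the mutant. The tail sheath gene (Pfl01_1154) had a log2 ratio of 0.68 (0.61 to 0.74), and the gene of the pyocin lytic enzyme (Pfl01_1172) 0.74 (0.43 to 1.07). Beside the run, mutS (Pfl01_1134) had a log2 ratio of -0.09 (-0.23 to 0.06) and recA (Pfl01_1175) 0.30 (0.22 to 0.39).

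**Figure D3:**
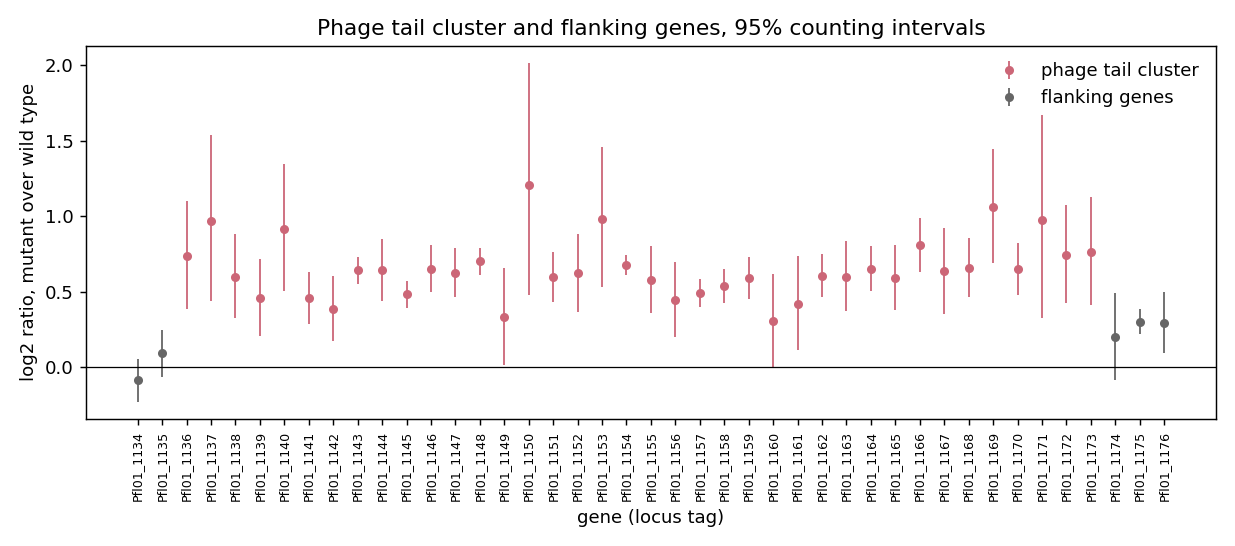
Log2 ratio of mutant over wild type (vertical axis) with exact 95% counting intervals (bars), for the 38 genes of the phage tail cluster (red) and 5 flanking genes (grey), in the order of their locus tags (horizontal axis), from 1 library per genotype. All 38 points lie above 0, with a median of 0.63. The 2 flanking genes on the left lie at -0.09 and 0.09, and those on the right at 0.20, 0.30 and 0.30.

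Outside this run the prophage list held 13 genes past the floor with a median log2 ratio of 0.09, percentile 62.3. The keyword for holins had also taken in 8 choline genes. Without these as well, the 5 genes left had a median of 0.98, percentile 100, and all 5 were higher in the mutant. The 5 others, named after their values were seen, were the lysozyme inhibitor gene Pfl01_0043, lrgA, the phage gene Pfl01_3496, an S-type pyocin gene (Pfl01_4759, 0.54) and the phage shock gene pspA (Pfl01_5044, 0.09). By annotation only Pfl01_3496 and Pfl01_4759 of these are phage or pyocin genes.

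The list of transposases and integrases had a median log2 ratio of 0.25 over 20 genes, 16 of them above 0 (percentile 99.9). The highest were an IS30-type element (Pfl01_2765, 0.54), a serine recombinase (Pfl01_3500, 0.51) and an integrase (Pfl01_3064, 0.49). In 2 pairs of members both genes had the same length and reads, as reads split between near-identical copies would give, and their ratios are uncertain. The 6 members of the whole list at or above 200 reads in a library, recA and recN among them, had a median of 0.02, percentile 52.7. The list of quorum sensing and secondary metabolites had a median of 0.32 over 13 genes, 8 above 0 (percentile 99.8). The genes of hydrogen cyanide synthase, which makes a toxic volatile, had log2 ratios of 0.83 (0.36 to 1.31) for hcnA (Pfl01_3516), 0.46 (0.16 to 0.77) for hcnB (Pfl01_3515) and 0.32 (-0.08 to 0.72) for hcnC (Pfl01_3514), none of them at 2-fold. A nonribosomal peptide synthetase gene (Pfl01_1847) had 0.55, and 2 regulator genes of the LuxR family had 0.69 (Pfl01_1863) and 0.65 (Pfl01_5708). These 2 were taken in by the family name, and KEGG matched them to the response regulators EvgA and FixJ. A further LuxR regulator gene (Pfl01_3531) had the lowest ratio, -0.54. Of the genes of this list, hcnB, hcnC and Pfl01_3531 were named after their values were seen. With no level floor this list lay at percentile 89.9, and with a floor of 200 reads at percentile 66.7.

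Median ratios below those of random lists were found for 4 lists. The list of the tricarboxylic acid cycle had a median log2 ratio of -0.13 over 22 genes, 17 below 0 (percentile 0.45). Examples within the cycle were the E2 component of 2-oxoglutarate dehydrogenase (Pfl01_1615, -0.40), sucA (Pfl01_1614, -0.30) and an isocitrate dehydrogenase (Pfl01_3594, -0.29). The last 2 were named after their values were seen. The gene aceK (Pfl01_1419), whose product controls isocitrate dehydrogenase, went the other way, from 105 to 180 reads (0.78, 0.43 to 1.15). By their names, the keywords had also taken in the methylisocitrate lyase gene prpB (Pfl01_1764, -0.39) and a methylcitrate synthase gene (Pfl01_1765, -0.33). Type VI secretion genes, which encode a contractile injection machine, had a median of -0.20 over 12 genes, 8 below 0 (percentile 0.39). The sheath gene impC (Pfl01_5594) had -0.67 (-0.96 to -0.38) and the hcp gene (Pfl01_2045) -0.44 (-0.75 to -0.14). With no level floor the list had 36 genes, a median of 0.01 and percentile 21.9. Translation factors and tRNA synthetases had a median of -0.08 over 39 genes (percentile 1.71). The list lay at percentile 2.95 with a floor of 10 reads and 2.72 with 200 reads. By symbols alone it had 7 genes, a median of -0.03 and percentile 47.6. The keywords for structural RNA found 0 rRNA or tRNA genes. They took in 32 genes of proteins instead, such as rRNA-modifying enzymes, with a median of -0.13, 24 below 0 (percentile 0.26). A pseudouridine synthase of 23S rRNA (Pfl01_4941) had -0.54 (-0.91 to -0.19). This list was therefore no measure of rRNA removal, and with a floor of 200 reads it lay at percentile 7.92.

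The other 19 lists with a percentile lay inside the central 95% of random lists. DNA repair and SOS genes had a median log2 ratio of 0.01 over 40 genes, from -0.37 for dinG (Pfl01_1225) to 0.40 for radC (Pfl01_5539). Oxidative stress defence had 0.01 over 27 genes, with a glutathione peroxidase gene (Pfl01_1654) at 0.69 (0.34 to 1.04), and sulfur assimilation and cysteine had 0.03 over 27. Iron-sulfur cluster assembly had -0.12 over 8 genes, with a cysteine desulfurase gene (Pfl01_3912) at -0.38 (-0.62 to -0.15). Iron uptake and siderophores had 0.10, nitrate, nitrite and nitrogen regulation 0.14, type IV pili 0.06, cold shock proteins 0.06, exopolysaccharide, biofilm and cyclic di-GMP 0.05, transcriptional regulators 0.05, the respiratory chain and ATP synthase 0.03 and phosphate uptake 0.03. Amino acid catabolism had -0.00, multidrug efflux -0.02, fatty acid biosynthesis and degradation -0.03, ribosomal proteins -0.03, flagella and chemotaxis -0.03, heat shock chaperones and proteases -0.04 and cell division and DNA replication -0.04. Restriction-modification had 3 genes past the floor (median 0.27), type II and type III secretion 2 (0.36) and the dnd keywords 1, so that these had no percentile. Of the 27 lists with a percentile, 8 lay outside the central 95%. The lists are not separate, since integrase genes beside the deletion were also on the list of transposases and integrases. The numbers 27 and 8 include the genes beside the deletion, a list whose members rest in part on a choice made after values were seen. Simulated libraries, which held counting error and no spread between cultures, put 6.5% of lists outside. Adjacent genes varied together in these libraries, and random lists of scattered genes leave that out.

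**Figure D4:**
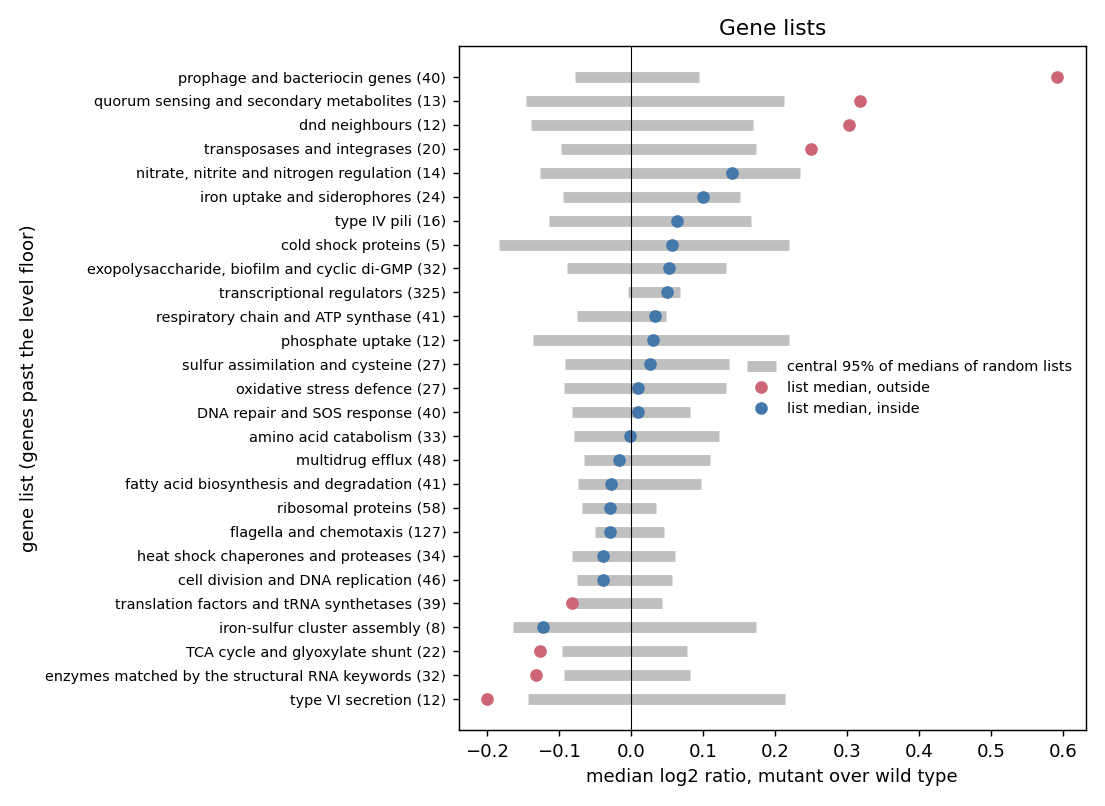
Median log2 ratio of mutant over wild type (horizontal axis) of each gene list with at least 5 genes past the level floor (vertical axis, number of genes in brackets), as points, with the central 95% of medians of 10000 random lists matched on level as grey bars. Of the 27 lists, 4 lie to the right of their bar and 4 to the left (red), and the prophage and bacteriocin list is farthest from its bar at 0.59.

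The authors' deposited table of called genes held 10 genes, 6 higher and 4 lower in the mutant. The 4 lower genes were the deleted ones. The 6 higher genes in the authors' deposited table were Pfl01_1797 (log2 ratio 1.64, false discovery rate 2.27e-34), Pfl01_1169 (1.06, 2.44e-07), Pfl01_2488 (1.02, 0.000123), Pfl01_0900 (1.04, 0.000353), Pfl01_3496 (1.04, 0.000557) and an amidase gene (Pfl01_5657, 1.85, 0.000565), which had 12 and 43 reads and was below the level floor used here. Of the 9 higher genes counted here, 5 were in the authors' deposited table of called genes. At a deposited false discovery rate of at most 0.05 and no fold limit, the authors' deposited table had 271 higher and 236 lower genes. Those values come from 1 library against another, and compare the libraries rather than the genotypes.

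Across the 3452 genes past the floor, the log2 levels of the libraries had a Pearson correlation of 0.976 and a Spearman correlation of 0.980, over genes, which are not independent replicates. Without the deleted genes the Pearson correlation was 0.988. The median log2 ratio was 0.01, the SD without the deleted genes was 0.27, and 95.5% of genes lay within 1.5-fold. Of the 157 genes beyond 1.5-fold, 120 were higher in the mutant and 37 lower. Of the 120 higher genes, 27 were in the phage tail cluster. With a floor of 200 reads 29 genes were higher and 8 lower, and 19 of the 29 were in the cluster. The interval excluded an equal level for 907 genes, 479 higher and 428 lower, where counting error alone gives about 173. The SD of the log2 ratio was 0.32 in genes of 50 to 100 reads and 0.16 in genes of at least 3000. The squared deviation from equality was 1.81 times the counting variance on average in the first class and 40.4 times in the second (medians 0.81 and 16.15). With no second culture of either genotype, the part of this that is spread between cultures or libraries cannot be separated from the effect of the mutation.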

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

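The alternatives that drop deleted genes (with or without another floor), choline genes, the phage tail cluster, housekeeping recombinases or copies, and the match on gene length, were added after the data were seen. No paired analysis was possible because each genotype had 1 library, and no library could be left out. The counts of genes at least 2-fold higher (9) and lower (4) were 6 to 9 and 4 under every scaling, pseudocount and unit, but moved with the floor and the threshold. With no floor they were 233 and 134, with 10 reads 128 and 57, and with 200 reads 1 higher. At 1.5-fold they were 120 and 37, at 4-fold 0 higher, and with the interval wholly beyond 2-fold 1 higher. Fewer reads give wider chance ratios and a stricter rule fewer genes by construction. Without the deleted genes 1 lower gene was left. All 4 deleted genes stayed at least 2-fold lower under each alternative run. The authors' deposited table had 4 genes at an absolute log2 ratio of at least 2 and 507 at a false discovery rate of 0.05 alone. The genome-wide agreement of the 2 libraries was a correlation of 0.951 with a floor of 200 reads. Without the deleted genes it was 0.988 at the main floor and 0.987 at 200 reads, so the drop came from the deleted genes. Of the lists, 2 lay outside the central 95% with a floor of 200 reads and 1 by symbols alone, the genes beside the deletion, which left 9 lists and not those of prophages, transposases or type VI secretion. With random lists matched on gene length 10 lay outside, as ribosomal proteins came to percentile 2.4 and transcriptional regulators to 99.0. The prophage median was 0.49 with no floor, 0.092 without the tail cluster and 0.98 without the cluster and the choline genes. The type VI secretion median turned to 0.009 with no floor, and the cause was not tested. Among list medians under alternatives, 284 of 306 values stayed within the counting error and 21 moved. Among ratios of named genes 814 of 822 stayed and 8 moved, of which 4 were of genes with no mutant reads. At 2132087 and 2117442 reads, 3452 of 5692 genes passed the floor, and fewer reads give wider intervals.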

Other observations

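The tests on the reads left in dndB, on fractional counts, on SOS genes and on low-level genes were chosen after the values were seen, as were the phage tail cluster and the SOS genes themselves. The scaling and gene length tests of the cluster therefore also rest on a choice made after values were seen. The SOS genes were 14 genes of the DNA damage response. Of these, recA (Pfl01_1175) had a log2 ratio of 0.30 (95% counting interval 0.22 to 0.39), recX (Pfl01_1176) 0.30 (0.09 to 0.50), a second lexA gene (Pfl01_3152) 0.53 (0.09 to 0.99), imuB (Pfl01_3150) 0.39 (0.00 to 0.78) and dnaE2 (Pfl01_3149) 0.30 (-0.02 to 0.63). The main lexA gene (Pfl01_3872) had 0.11 (-0.14 to 0.36), recN (Pfl01_0761) 0.21 (-0.02 to 0.43), uvrA (Pfl01_5051) 0.08 and dinB (Pfl01_1195) -0.03, and dinG (Pfl01_1225) was lower, at -0.37 (-0.56 to -0.19). Around xanthine dehydrogenase the ratio was highest in Pfl01_1797, at 1.64. The large subunit gene (Pfl01_1796) had 0.41 (0.06 to 0.76), the accessory factor gene (Pfl01_1795) 0.20 and guanine deaminase (Pfl01_1794) 0.21. The regulator gene of the GntR family on the other side (Pfl01_1798) had -0.30 (-0.51 to -0.08). These genes near Pfl01_1797 were named after their values were seen.

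The 38 genes of the phage tail cluster were higher in the mutant library with a median log2 ratio of 0.63. The highest median of 5580 other windows of 38 adjacent genes was 0.51 (Pfl01_3332 to Pfl01_3369). Those windows held genes of any level, while all 38 genes of the cluster passed the level floor, so like was not set against like. Over 6 scalings the median of the cluster was never under 0.60. Random lists matched on gene length reached 0.13 at their upper limit, and 0 of the 38 genes had a fractional count in either library. The values for scaling and gene length argue against these 2 as the cause. The fractional counts cannot decide on reads shared with copies, since only 25 genes of the wild type and 21 of the mutant had any. How the counting program, which was not given, placed such reads is unknown. A damage response may be tied to the cluster, since R-type pyocins are induced through RecA in related species: the 14 SOS genes had a median of 0.16, at percentile 98.9 of random lists, but the 11 that do not lie beside the cluster had 0.09, at percentile 82.8, and the DNA repair list fixed in advance had percentile 65.1, so this stays open. The bound set for a link, a median above the central 95% of random lists, was met by the 14 genes, and the check without the 3 genes beside the cluster was added after that value was seen. The loss of the dnd genes, or of the modification, also stays open, as does any other difference between the 2 cultures. Genotype and library cannot be told apart.

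The mutant library kept 16 reads of dndB, 3.55% of its wild type level. Wild type RNA or reads carried over at that share would have given 51.9 reads in the other 3 deleted genes, or 29.7 at the lower 95% limit of the 16 reads, where 0 were seen and a count of 0 allows 3. This argues against carry-over. A part of dndB left beside the deletion could give such reads, but the tables give 1 number per gene and the 16 reads cannot be placed within it.

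Genes with few reads were slightly higher in the mutant library. The summed log2 ratio was 0.23 (0.15 to 0.31) for the 378 genes with 5 to 10 reads, 0.16 with 10 to 20, 0.11 with 20 to 50 and 0.07 with 50 to 100, against -0.01 for the 186 genes with at least 2000. An even background of reads over the genome would add the same number of reads per kilobase to every gene. The gain was 0.94 reads per kilobase (0.59 to 1.30, redrawing genes) in genes under 10 reads per kilobase, 1.31 (0.85 to 1.75) from 10 to 20, 2.05 (1.40 to 2.71) from 20 to 40, 3.02 (2.11 to 4.00) from 40 to 80 and 5.16 (3.51 to 6.86) from 80 to 160. The bound set for excluding it, a gain below the intervals of both next classes, was met for 1 of the 2, so the test as set stays open, while the classes from 40 upward and these intervals, added after that outcome was seen, argue against it as the whole cause.

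One hypothesis was that the differences between the libraries follow the order of genes, as joint changes of adjacent genes would give. Over 2641 pairs of adjacent genes past the floor, without the deleted genes, the log2 ratios had a Pearson correlation of 0.24, above the central 95% of -0.04 to 0.04 in 1000 simulated pairs of libraries that differed by counting error alone. For genes 5, 10 and 20 apart it was 0.08, and for genes 50 apart -0.02. Without the tail cluster it was 0.18 for adjacent genes, 0.11 for genes 2 apart, -0.00 for genes 5 apart and 0.01 for genes 10 apart. Part of the spread between these libraries may thus be shared by neighbours, whether from the genotype or from the cultures, which these data do not separate.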
